A study of Fagopyrum tataricum with 12 samples.

How the data were processed

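The series measured RNA from 4 tissues of Tartary buckwheat (Fagopyrum tataricum, cultivar XiQiao 2) at flowering, with 3 libraries each from flower, leaf, root and stem, 12 libraries in all. Per the labels' protocols, plants were field-grown, tissue was frozen at once and RNA was taken with Trizol. The series text names a BGISEQ-500 instrument, whereas the extract protocol names an Illumina kit, and the instrument is given here after the series text. The labels state that 3 plants gave the 3 replicates and that tissues came from the same individual, but not whether a replicate number names a plant. Comparisons were therefore unpaired, and pairing by number was checked rather than assumed. The p-values for single genes and for library measures below measure the spread between these samples. Those of gene ontology overlaps and of shuffled neighbouring genes instead treat genes as units. Gene list tests at a preset correlation also rest on that assumed value.

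The deposited expression table gives FPKM (fragments per kilobase of transcript and per total of mapped fragments) for 30875 genes per the file headers, of which 29706 carry FtPinG and 1169 carry BGI_novel identifiers. Bowtie2 (version 2) is named in the submitters' processing notes without a role. The quantifier, the gene annotation and the genome build are not given in the sources used here. The deposited SNP and indel tables hold, per site and library, the called non-reference allele as bases or a dash (unit: other, an allele and not a count). They give no depth, quality or zygosity, and a dash stands for a reference allele or an uncalled site. Coordinates are those of the deposited tables, on chromosomes named Ft1 to Ft8 of an unnamed build, and no position was converted. FPKM values carry no read totals, so absolute depth is unknown and no counting interval or detection floor was computed. Relative depth was read from the modal ratio of genes between 0.15 and 1 FPKM, and was 0.901 to 1.035 of the first flower library.

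Gene descriptions came from the variant tables alone, which name 14471 genes. Of these, 14276 were in the expression table and 13575 had a description, covering 52.68% of the 22350 genes tested. For 8596 tested genes the description was informative, and genes without variants could not be named. Paralogs of multigene families were kept as separate genes, and counting could split reads between near-identical copies.

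Genes with an FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1) in limma 3.58.1 (R 4.3.3) with an intensity trend, in 1 fit of all 12 libraries with tissue as the only term. A gene passed a comparison at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. The 6 pairs of tissues were compared, and a gene was called highest or lowest in a tissue when it passed in the same direction in all 3 of that tissue's pairs. Each tissue was also contrasted with the mean of the other 3, and log2 differences quoted for single genes are those contrasts unless a pair is named. Log2 differences of genes near 0 in a tissue depend on the pseudocount of 1 and are not bounds. An F test across tissues, the tissue specificity index tau (specific at 0.9 or more), principal components, and exact two-sided permutation tests of library measures were added. With 3 libraries against 3 the smallest exact p is 0.1.

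The tests, the alternatives, 19 gene lists and the rule for naming genes were fixed before the data were examined. Lists were text patterns matched to gene descriptions and tested with limma's camera at a preset correlation of 0.01 on each tissue contrast, giving 76 list tests adjusted together, and again with the correlation estimated per list. Camera compares a list with the other genes, so a list can test as higher while its mean is negative. Counts of list members used the adjustment over all genes; adjusted over the list alone, they differed for 2 lists, as given in the report. Several patterns were broader than intended. The housekeeping pattern "actin" also matched "interacting", so that list held 163 tested genes against 66 when matched at word starts, and the list of other organisms held 13 against 2. The glycerate dehydrogenase pattern matched D-3-phosphoglycerate dehydrogenase. The cell cycle pattern for D-type cyclins also matched descriptions with "cyclin-dependent", among them inhibitors of cyclin-dependent kinases. Results use the lists as written, and matching at word starts was added after the members had been seen.

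Named genes followed the fixed rule. Per tissue, they were the 8 highest and 4 lowest described genes by the smallest of the 3 pairwise log2 differences, among genes called highest or lowest and with a mean of at least 10 FPKM in the top tissue. Per list and tissue, up to 4 passing members with the largest mean FPKM were added, as was the most abundant member of each list. Members named for a list count of 5 or fewer that fall outside this rule were chosen after their values were seen.

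Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios and quantile scaling, rescaling to a common total, the replicate number as a replicate block, fold thresholds, limma with a robust fit or no trend, fits of 2 tissues only, and leaving out each library. Leave-one-out was planned with the expression filter applied again. That drops a gene expressed in a single tissue, since 2 libraries cannot meet the minimum of 3, so a version that keeps the tested genes was added after this was seen. Median-of-ratios factors came from 12563 genes above 1 FPKM in every library. SNP sharing between libraries was also computed for sites in genes with at least 5 FPKM in all 12 libraries, a restriction added after the full tables were seen. Gene ontology terms in the variant tables' descriptions were tested by hypergeometric overlap.

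Simulated data for 12 libraries and 22350 genes were drawn with each gene's mean and residual spread over all tissues. Per size of change, 100 genes were altered in flower, all with a mean log2 value over 3, so low genes were not covered. In flower against leaf, 89% of genes changed by 1.5 log2 and 100% of those changed by 3 were recovered, with 6 false calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and statmod 1.5.0 for the block fit. No expression column was left out (0 columns), and 0 pairs of libraries had identical values. Heterozygous shares and depth minimums of variants could not be computed from the tables. No genome sequence was used, so gene positions are given only by the variants within a gene, and gene length and base composition were not analysed here.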

Results

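RNA abundance was measured as FPKM in flower, leaf, root and stem of Tartary buckwheat at flowering, with 3 libraries per tissue, and SNP and indel calls were given for the same 12 libraries. The series names quantification of the transcriptome as its purpose, and the design allows each tissue to be compared with the others. Summed FPKM per library ranged from 740325 to 853200, and depth judged from low genes was 0.901 to 1.035 of the first flower library. Values are means with SD and n = 3 libraries per tissue.

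The number of genes detected and the share of the most abundant ones were compared between tissues. At 1 FPKM or more, 20064 ± 281 genes were detected in flower (SD, n = 3), 19893 ± 197 in root, 17286 ± 229 in stem and 15563 ± 640 in leaf. The exact permutation p was 0.1 (adjusted p = 0.12) for every pair except flower and root (p = 0.4), and 0.1 is the smallest this design allows. The gap between leaf and stem hung on scaling: after median-of-ratios scaling 17156 ± 106 genes were detected in leaf, 17248 ± 147 in stem, 18926 ± 130 in root and 19466 ± 110 in flower. The 10 most abundant genes held 45.5% ± 3.10 of the FPKM in leaf, 33.3% ± 5.04 in flower, 32.2% ± 2.08 in stem and 27.6% ± 0.481 in root. For that share the exact permutation p was 0.1 (adjusted p = 0.15) for the 3 pairs with leaf and for root against stem, 0.2 for flower against root and 0.9 for flower against stem. The undescribed BGI_novel_G000042 was the top gene of each library, at 60297 to 93385 FPKM.

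Libraries grouped by tissue. Correlations of log2 values across genes, which are not independent replicates, were 0.9595 to 0.9937 within tissues and 0.4705 to 0.8235 between them, lowest for leaf with root and highest for flower with stem. The F test of limma called 21466 of 22350 genes different among tissues. By tau, 861 genes were specific to root and 706 to flower, against 37 to leaf and 34 to stem. With a pseudocount of 0.1 these were 526, 530, 14 and 8, so the order of root and flower hung on the pseudocount.

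**Figure D1:**
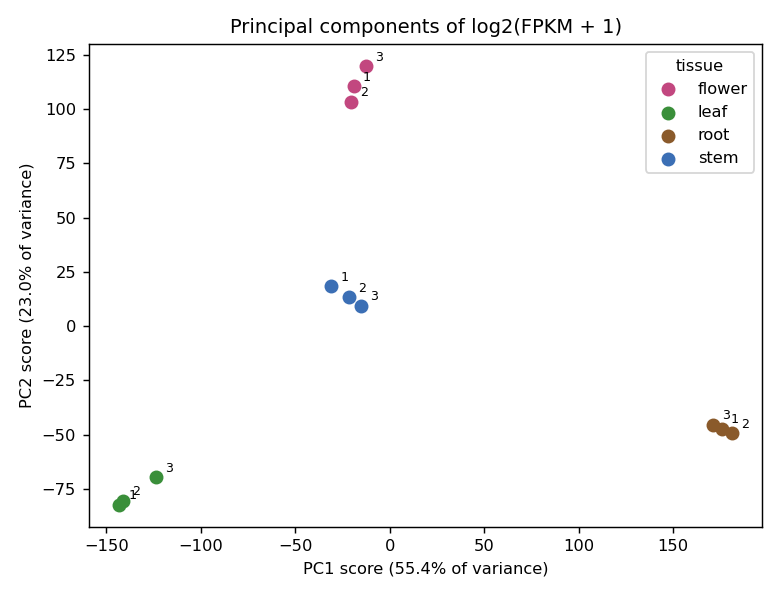
Scores of the 12 libraries (points, numbered by replicate and coloured by tissue) on the first 2 principal components of log2(FPKM + 1). PC1, with 55.4% of the variance, placed root apart from leaf, and PC2, with 23.0%, placed flower apart from leaf and root.

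More lignin and cell cycle genes were called higher in flower than in leaf, and more light reaction genes higher in leaf. Cinnamoyl-CoA reductase 1 (FtPinG0009234700.01), a lignin branch enzyme, stood at 2051 ± 212 FPKM in flower and 8.54 in leaf. Carbonic anhydrase (FtPinG0004782300.01), which interconverts carbon dioxide and bicarbonate, stood at 44.3 in flower and 1572 ± 61.2 in leaf. Of 42 cell cycle genes 26 were higher in flower and 0 in leaf, of 47 lignin branch genes 24 and 0, and of 34 light reaction genes 1 and 24. Limma called 8736 genes higher in flower and 1293 higher in leaf, 87.1% towards flower, with a median log2 difference over all genes of 0.78. After median-of-ratios scaling the calls were 4183 and 2754, or 60.3%, with 13 cell cycle and 14 lignin genes higher in flower and 0 and 2 in leaf.

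Flower and root differed in photosynthesis on one side and phenylpropanoid entry on the other. Of 34 light reaction genes 29 were higher in flower and 1 in root, whereas of 8 phenylpropanoid entry genes 1 was higher in flower and 6 in root. Cinnamate 4-monooxygenase (FtPinG0009242400.01), which makes coumaric acid, stood at 2.86 FPKM in flower and 181 ± 22.1 in root. Chlorophyll a-b binding protein 3 (FtPinG0002327100.01), a light-harvesting protein, stood at 2037 in flower and 6.87 in root. Limma called 3815 genes higher in flower and 4357 higher in root. The median log2 difference was -0.14, and the majority turned from 46.7% towards flower to 53.1% after median-of-ratios scaling.

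More flavonoid core and heat shock genes were called higher in flower than in stem. Of 8 flavonoid core genes 6 were higher in flower and 0 in stem, of 38 heat shock genes 18 and 1, and of 34 secondary wall genes 8 and 12. One flavonol synthase (FtPinG0006907000.01) stood at 72.8 ± 13.7 FPKM in flower and 0.16 in stem. Alpha tubulin (FtPinG0005325300.01), a microtubule subunit, stood at 972 in flower and 3625 ± 333 in stem. Limma called 3859 genes higher in flower and 1687 higher in stem, 69.6% towards flower with a median log2 difference of 0.29, against 58.7% after median-of-ratios scaling.

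Leaf against root gave the most calls of the pairs, with photosynthesis on the leaf side and phenylpropanoid and lignin genes on the root side. Of 34 light reaction genes 30 were higher in leaf and 2 in root. Of 8 phenylpropanoid entry genes 7 were higher in root and 0 in leaf, and of 47 lignin genes 28 and 5. Fructose-bisphosphate aldolase 1 (FtPinG0001373100.01) stood at 2291 ± 67.8 FPKM in leaf and 0.42 in root, and caffeic acid 3-O-methyltransferase (FtPinG0009324600.01), a lignin enzyme, at 40.6 in leaf and 966 ± 337 in root. Limma called 2345 genes higher in leaf and 11372 higher in root, 17.1% towards leaf with a median log2 difference of -1.03. After median-of-ratios scaling the calls were 3829 and 5522, or 40.9% towards leaf, with 25 lignin genes higher in root and 8 in leaf.

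Leaf against stem set photosynthesis against wall genes. Of 34 light reaction genes 22 were higher in leaf and 3 in stem, and of 34 secondary wall genes 4 and 19. Gibberellin-regulated protein 6 (FtPinG0006350100.01) stood at 0.857 FPKM in leaf and 623 in stem, and the large chain of ribulose bisphosphate carboxylase (FtPinG0005967800.01), the enzyme that fixes carbon dioxide, at 1961 ± 286 and 251. Limma called 1988 genes higher in leaf and 6351 higher in stem, 23.8% towards leaf with a median log2 difference of -0.37, against 48.0% after median-of-ratios scaling, where 6 secondary wall genes were higher in leaf and 19 in stem.

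Root against stem set phenylpropanoid, lignin and regulator genes against photosynthesis genes. Of 8 phenylpropanoid entry genes 7 were higher in root and 0 in stem, of 47 lignin genes 24 and 7, of 93 MYB and bHLH regulators 40 and 6, and of 34 light reaction genes 1 and 29. MYB59 (FtPinG0008427400.01), a transcription factor, stood at 85.7 ± 15.0 FPKM in root and 4.68 in stem, and the nitrate and peptide transporter family protein 1.2 (FtPinG0001054500.01) at 5.64 and 287 ± 21.8. Limma called 5931 genes higher in root and 2419 higher in stem, 71.0% towards root with a median log2 difference of 0.41, against 54.9% after median-of-ratios scaling. Member counts for pairs of tissues carry no list test.

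**Figure D2:**
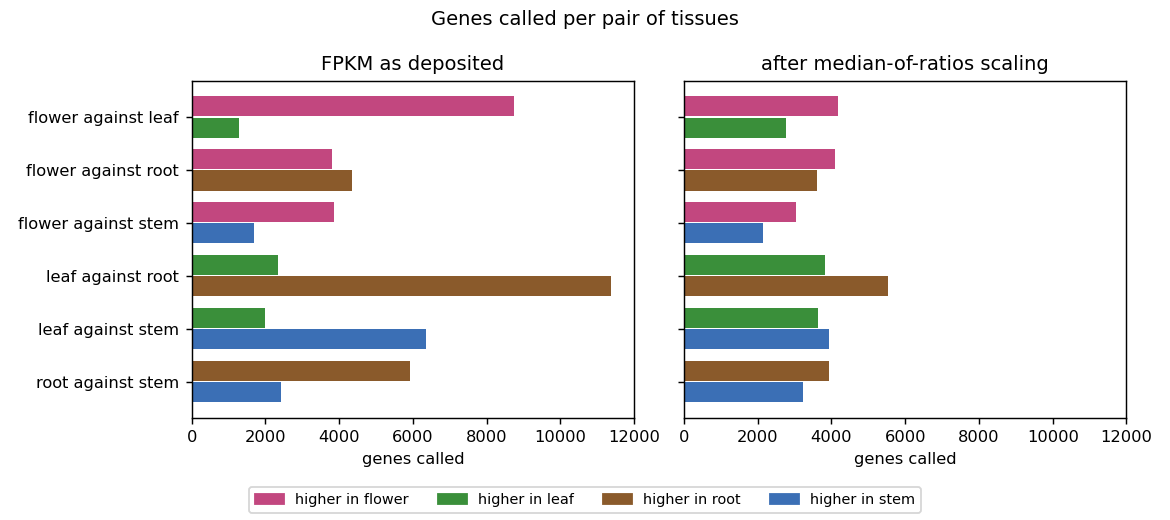
Number of genes called by limma per pair of tissues (bars, coloured by the tissue in which the gene was higher), for FPKM as deposited and after median-of-ratios scaling. In leaf against root 11372 genes were higher in root as deposited and 5522 after scaling.

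The genes named as highest in flower were of several kinds. Formin-like protein 20 (FtPinG0001989400.01, chromosome Ft4), of a family that nucleates actin filaments, stood at 744 ± 77.1 FPKM in flower (SD, n = 3) and under 1 in each other tissue, a log2 difference of 9.41 (SE 0.121, limma adjusted p = 2.52e-14). A pair of trypsin inhibitor genes on Ft1, FtPinG0004975000.01 and FtPinG0004974800.01, with variants listed at 50307903 and 50306853, stood at 727 ± 143 and 360 ± 162. Germin-like genes FtPinG0002943700.01 and FtPinG0008959100.01 stood at 468.5 ± 74.7 and 170.2 ± 23.2. A caffeic acid 3-O-methyltransferase 1-like gene (FtPinG0007033000.01) reached 106 ± 15.7 and was listed at 0 in root, a dirigent protein (FtPinG0007430900.01) reached 149 ± 37.9, and a cell wall invertase (FtPinG0005000000.01), which splits sucrose outside the cell, 85.8 ± 25.4. Limma called 1590 genes highest and 57 lowest in flower, against 972 highest with a minimum of 5 FPKM and 123 lowest after median-of-ratios scaling. The lowest with names were a nicotianamine synthase-like gene (FtPinG0002192800.01, log2 -4.55), the SVP gene (FtPinG0006903300.01, -4.31), acid phosphatase 1 (FtPinG0008802500.01, -4.00) and the calcium-binding protein CML49 (FtPinG0005900600.01, -2.93). SVP belongs to the MADS-box family and represses flowering in Arabidopsis; it stood at 0.293 in flower and 51.4 ± 7.19 in stem.

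Flavonoid core genes rose in flower: 6 of 8 members passed higher and 0 lower (mean log2 2.23, camera adjusted p = 0.0197; adjusted p = 0.532 with an estimated correlation). Chalcone isomerase (FtPinG0002790600.01) stood at 108 ± 10.1 FPKM (log2 1.59), flavonoid 3'-hydroxylase 2 (FtPinG0002353900.01) at 174 ± 32.8 (1.28) and a flavonoid hydroxylase-like gene (FtPinG0003192500.01) at 70.1 ± 5.09 against 1.02 in leaf, 1.20 in root and 1.57 in stem (0.985 without stem library 3). A pair of flavonol synthase genes on Ft7 differed from each other. FtPinG0006907100.01 stood at 510.2 ± 87.6 in flower, 505 ± 192 in leaf and 519.9 ± 233 in stem but 7.13 ± 2.99 in root, whereas FtPinG0006907000.01 stood at 72.8 ± 13.7 in flower, 42.9 ± 4.47 in root and 0.883 in leaf (0.3 without the third leaf library). Flavonol synthase makes the aglycones of flavonols such as rutin, the best known flavonoid of this crop. An anthocyanidin 3-O-glucosyltransferase-like gene (FtPinG0009431800.01) was the 1 of 3 glycosyltransferases that rose in flower, at 237 ± 51.7 (log2 2.96; list adjusted p = 0.891). The single tested gene of the anthocyanin branch, leucoanthocyanidin reductase (FtPinG0002428800.01), passed higher in flower at 6.85 FPKM (log2 1.97; list adjusted p = 0.576). After median-of-ratios scaling the 3'-hydroxylase 2 fell under the fold threshold, at a log2 difference of 0.96.

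Earlier and side steps of the pathway split in flower. Of 8 phenylpropanoid entry genes 1 rose, a phenylalanine ammonia-lyase (FtPinG0005713400.01) at 302 ± 32.0 FPKM, and 3 fell (camera adjusted p = 0.115). Of 47 lignin branch genes 14 rose and 12 fell; the list mean was 0.40, its median was -0.17 and the test leaned down (adjusted p = 0.239). After median-of-ratios scaling 13 rose and 14 fell, with a mean of 0.23 and a median of -0.43. Cinnamoyl-CoA reductase 1 (FtPinG0009234700.01) was the largest of them, with a log2 difference of 7.86, 73.5 FPKM in stem and 0.343 in root. Its stem mean was 40.1 without the first stem library, and its root mean 0.215 without the first root library. The secondary wall list had 9 genes up and 2 down (mean 0.13, median -0.09, test down, adjusted p = 0.158), or 6 up and 6 down with a mean of -0.10 after that scaling. Of the 2 down, FtPinG0004398100.01 lost its call without flower library 2 (log2 -0.95).

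**Figure D3:**
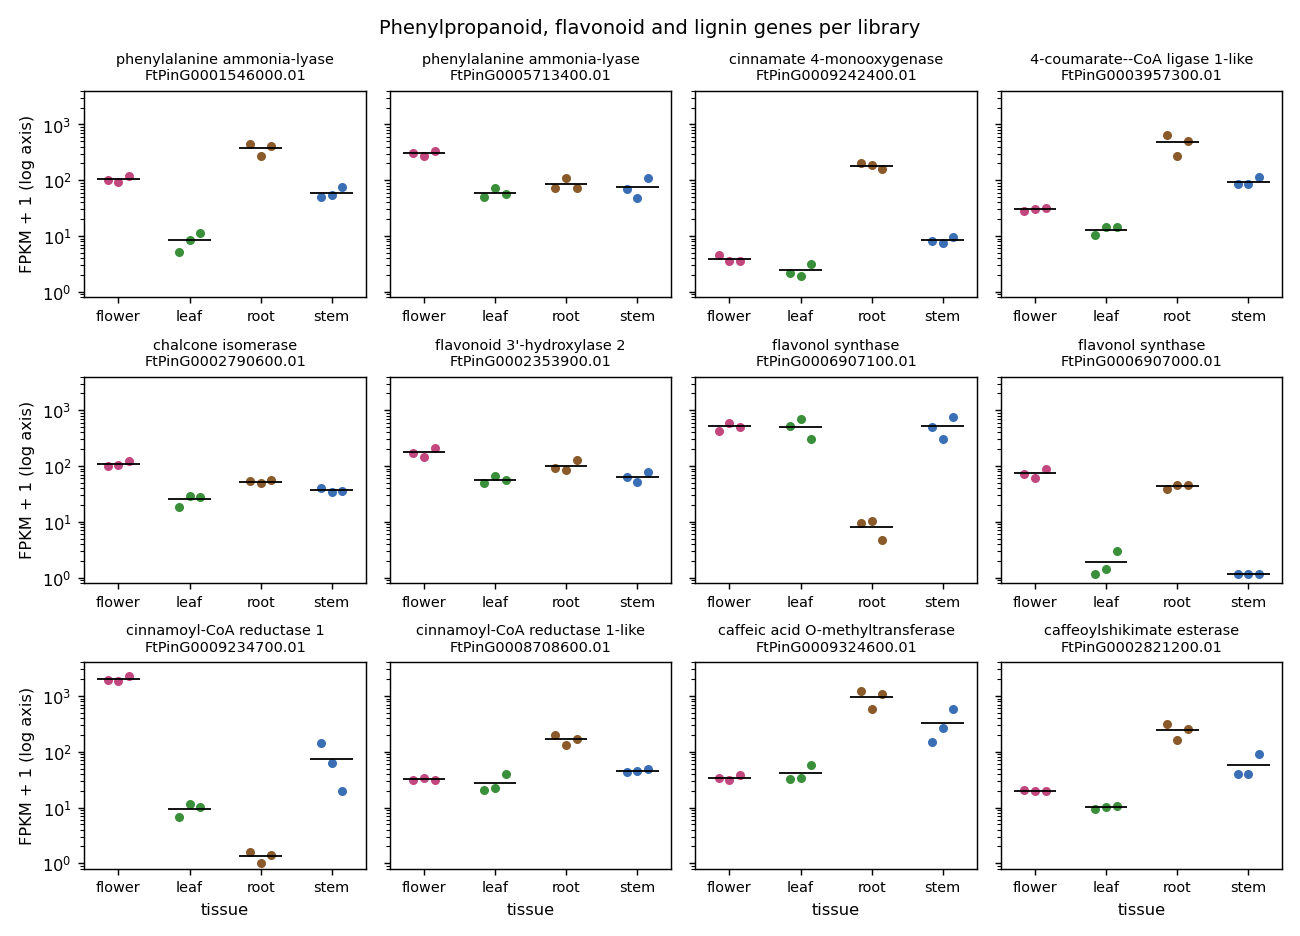
FPKM + 1 (log axis) of 12 phenylpropanoid, flavonoid and lignin genes in each library (points), with the tissue mean as a line, n = 3 per tissue. Cinnamoyl-CoA reductase 1 (FtPinG0009234700.01) stood at 2051 FPKM in flower and 8.54 in leaf, and the methyltransferase FtPinG0009324600.01 at 33.5 in flower and 966 in root.

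Floral identity genes did not move as 1 group. Of 13 MADS-box genes 4 rose and 4 fell in flower (mean 0.65, test down, camera adjusted p = 0.911). The rises included a PISTILLATA-like gene (FtPinG0002919400.01) at 65.5 ± 1.78 FPKM, listed at 0 in leaf and stem, and APETALA3-like genes FtPinG0002738700.01 at 25.1 ± 1.88 and FtPinG0002154600.01 at 18.2, all of the class that specifies petals and stamens. The fourth was AGL15 (FtPinG0002461800.01) at 8.96. Those that fell were SVP (FtPinG0006903300.01), a JOINTLESS-like gene (FtPinG0007644000.01), AGL19 (FtPinG0008279400.01) and a MADS-box gene (FtPinG0002572100.01). Of 15 pollen and anther genes 3 rose and 1 fell (mean 0.26, or 0.02 after median-of-ratios scaling, test down, adjusted p = 0.896), and pollen-specific leucine-rich repeat extensin 3 (FtPinG0004385500.01), at 3.62 ± 0.329, was listed at 0 in the other tissues. Cell cycle genes rose, 14 of 42 with 0 lower (mean 0.87, adjusted p = 0.00719; adjusted p = 0.933 with an estimated correlation). Their named members were histones, which package DNA: an H2A (FtPinG0008429400.01) at 116 ± 10.6 (log2 3.08), H2A.1 (FtPinG0006469700.01) at 71.9 (1.87) and H3.3 (FtPinG0009090100.01) at 963 ± 91.4 (1.12), the last at 0.79 after median-of-ratios scaling.

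Heat shock genes also rose in flower, 14 of 38 with 0 lower (mean 1.18, camera adjusted p = 0.0131; adjusted p = 0.913 with an estimated correlation), among them the chaperones HSC70-2 (FtPinG0009469200.01) at 256 ± 97.9 FPKM and FtPinG0009470100.01 at 202 ± 78.1. The most abundant member, HSP90-2-like (FtPinG0007341000.01), did not pass, with 442 in flower, 195 in leaf, 249.98 in root and 382 in stem. After median-of-ratios scaling the heat shock risers FtPinG0003839000.01 and FtPinG0009429700.01 fell under the fold threshold (log2 0.86 and 0.71). HSC70-2 and FtPinG0009470100.01 stayed above it (1.54 and 1.74). Root ion and water uptake genes fell, 16 of 60 against 7 higher (adjusted p = 0.000435; adjusted p = 0.883 with an estimated correlation), such as an aquaporin PIP2-4-like gene (FtPinG0009899700.01) at 51.3 in flower and 480.02 in root. Light reaction genes passed higher than the mean of the other tissues for 18 of 34 members (camera adjusted p = 0.0113, or 0.913 with an estimated correlation), a count of 7 after median-of-ratios scaling, against a list mean of -4.99 in root. Their list call in flower was lost with a pseudocount of 5 (camera adjusted p = 0.103). Of 37 starch and sucrose genes 9 rose and 1 fell (adjusted p = 0.892), among them the cell wall invertase FtPinG0005000000.01 (log2 6.37) and granule-bound starch synthase 1 (FtPinG0005565800.01) at 78.3 ± 13.4 (log2 3.09). Other lists did not pass in flower. Their higher and lower counts were 1 and 0 for Calvin cycle (adjusted p = 0.778; FtPinG0000423500.01, whose call was lost without any 1 of 4 libraries, at log2 0.99 without flower library 3), 13 and 11 for endodermis and peroxidase (0.189; mean 0.52, median -0.02, test down), 17 and 3 for housekeeping (0.8004; mean 0.23, test down), 0 and 0 for ribosomal proteins (0.911; test down against a mean of 0.24), and 0 and 0 for other organisms (0.785; mean 0.15, test down). At an unadjusted limma p under 0.05 those last 2 lists had 25 higher and 0 lower, and 7 higher and 3 lower. MYB and bHLH regulators gave 23 and 7 (0.733), or 24 and 7 adjusted over the list alone. After median-of-ratios scaling the counts were 17 and 12 for these regulators, 7 and 4 for housekeeping and 0 and 1 for Calvin cycle. The means were then 0.00 for housekeeping, -0.06 for ribosomal proteins and -0.10 for other organisms, so their positive signs did not hold, and the median of endodermis and peroxidase was -0.31.

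The genes named as highest in leaf were of several kinds. HEADING DATE 3A (FtPinG0008101900.01), a mobile flowering signal in rice, stood at 36.2 ± 11.1 FPKM in leaf (SD, n = 3; log2 4.63). Wall-associated receptor kinases FtPinG0006327100.01 and FtPinG0007523100.01 stood at 49.2 ± 26.8 and 26.9, the second at 16.9 without the third leaf library. A WSD1-like gene (FtPinG0004759800.01), of a family that makes wax esters, stood at 18.5 ± 6.53, the sugar exporter SWEET12-like (FtPinG0005490000.01) at 35.8 ± 15.2 and a serine incorporator (FtPinG0005019500.01) at 56.3 ± 1.37. Carbonic anhydrase (FtPinG0004782300.01) and fructose-bisphosphate aldolase 1 (FtPinG0001373100.01) differed by 6.36 and 6.11 log2, the former with a limma adjusted p of 2.52e-11. Limma called 982 genes highest and 3807 lowest in leaf, against 2048 and 1279 after median-of-ratios scaling. The lowest with names were gibberellin-regulated protein 6 (FtPinG0006350100.01, log2 -6.56), an endo-1,3;1,4-beta-glucanase-like gene (FtPinG0001978800.01, -6.20), a leucine-rich repeat extensin (FtPinG0002125600.01, 0.623 in leaf and 197 in flower) and the plasmodesmata callose-binding protein 3 (FtPinG0001253200.01, -5.46).

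Light reaction genes rose in leaf, 28 of 34 with 1 lower (mean 2.71, camera adjusted p = 5.33e-32; adjusted p = 0.0740 with an estimated correlation). The 1 that fell was a root-type ferredoxin--NADP reductase (FtPinG0004266100.01), a form that works outside photosynthesis, at 6.96 FPKM in leaf and 63.7 in root. Chlorophyll a-b binding protein 3C (FtPinG0002327400.01) stood at 4582 ± 427 FPKM, with 1837 ± 224 in flower and 4119.8 ± 511 in stem, and protein 8 (FtPinG0001195000.01) at 1517 ± 69.2. Photosystem I subunit VI-2 (FtPinG0004740200.01) stood at 1993 ± 131 (log2 3.60). Of 11 Calvin cycle and photorespiration genes 7 rose and 3 fell (mean 1.26, or 2.01 after median-of-ratios scaling, adjusted p = 2.38e-06; adjusted p = 0.158 with an estimated correlation). The rises included the large chain of ribulose bisphosphate carboxylase (FtPinG0005967800.01, log2 4.59), phosphoribulokinase (FtPinG0004432900.01) at 896 ± 42.7 (5.24) and glycine cleavage protein H (FtPinG0000423500.01) at 675 ± 29.7 (4.71). D-3-phosphoglycerate dehydrogenase 2 (FtPinG0002853400.01), an enzyme of serine synthesis that the list matched by name, fell by 4.197 log2. Its leaf mean of 4.68 FPKM was 2.52 without the third leaf library. The others that fell were a glycine cleavage H-protein (FtPinG0005671800.01) at 4.54 and ribulose bisphosphate carboxylase/oxygenase activase (FtPinG0004218000.01) at 0.333 against 21.1 in stem.

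With FPKM as deposited, all other lists had more members lower than higher in leaf, except glycosyltransferases, against a median of all genes of -0.82 (-0.23 after median-of-ratios scaling). Of 163 housekeeping genes 94 fell and 2 rose (mean -1.13, camera adjusted p = 0.0109; adjusted p = 0.933 with an estimated correlation), or 38 and 6 with a mean of -0.45 after that scaling; alpha tubulin (FtPinG0005325300.01) fell by 3.38. Cell cycle genes fell in 21 of 42 with 0 higher (adjusted p = 0.0504) and all 8 phenylpropanoid entry genes fell (mean -2.22, adjusted p = 0.156), with 12 and 6 falling after scaling. The ammonia-lyase FtPinG0001546000.01 stood at 7.41 FPKM, and FtPinG0005713400.01 lost its call without leaf library 1 (log2 -0.93), root library 2 (-0.98) or stem library 3 (-0.94). Lignin genes fell in 28 of 47 with 3 higher (adjusted p = 0.453), secondary wall genes in 21 of 34 with 1 higher (0.759), endodermis and peroxidase genes in 26 of 46 with 4 higher (0.733) and MYB and bHLH regulators in 46 of 93 with 3 higher (0.363), such as MYB11 (FtPinG0008533900.01) at 1.06 in leaf (0.52 without leaf library 2) and 24.9 in flower. After scaling these counts were 25 lower and 4 higher, 13 and 4, 19 and 5, and 22 and 9. Of the 3 lignin risers, FtPinG0004664600.01 and FtPinG0006688900.01 lost their calls without leaf library 3 (log2 0.93 and 0.75). Flavonoid core genes gave 4 lower and 1 higher (0.960), floral MADS 5 and 1 (0.911), and pollen 7 and 1 (0.891), or 2 and 1, 4 and 1, and 2 and 2 after scaling. The riser among the MADS-box genes was a JOINTLESS-like gene (FtPinG0007644000.01) at 25.5 ± 10.9.

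A further 6 lists had a negative mean in leaf but tested higher than other genes, none past the threshold. They included ion uptake with 28 of 60 lower and 6 higher (mean -0.72, camera adjusted p = 0.527), starch and sucrose with 17 of 37 and 4 (-0.54, 0.527), heat shock with 16 of 38 and 5 (-0.73, 0.531) and ribosomal proteins with 2 of 81 and 0 (-0.31, 0.0501), namely L18a-like (FtPinG0000251100.01) at 23.4 and L7-1-like (FtPinG0001402400.01) at 11.5. After median-of-ratios scaling the lower and higher counts were 15 and 12, 11 and 10, 8 and 7, and 0 and 8, with means of -0.08, 0.00 and -0.05 for the first 3 lists. The 2 ribosomal genes then differed by -0.66 and -0.85 log2, and the ribosomal mean was 0.57, or 0.24 after quantile normalization. Among the rises, the large subunit 3 of glucose-1-phosphate adenylyltransferase (FtPinG0007393600.01), which supplies starch synthesis, stood at 92.3 ± 3.31 FPKM and the stromal chaperone HSP70 (FtPinG0007128300.01) at 333. The most abundant ribosomal protein gene, L29-1 (FtPinG0006808700.01), did not pass, at 232 in leaf and 391 in flower. The list of other organisms had 3 of 13 lower and 2 higher (mean -0.02, adjusted p = 0.158), or 0 lower and 3 higher with a mean of 0.67 after scaling; its most abundant riser was a Cyanobacterial aminoacyl-tRNA synthetase domain gene (FtPinG0002598500.01) at 240.2 ± 30.4, a conserved plant protein named for a domain. Glycosyltransferases had 0 passing of 3 in limma (1 higher and 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.539), with a mean of -0.28 that turned to 0.33 after scaling. The anthocyanin branch gene (FtPinG0002428800.01) fell by 1.55 log2 (list adjusted p = 0.911).

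The genes named as highest in root were of several kinds. The MLP-like protein 34 (FtPinG0008960100.01), of a family related to pathogenesis-related proteins, stood at 4884 ± 1893 FPKM in root (SD, n = 3) and under 1 elsewhere (log2 12.11, SE 0.195, limma adjusted p = 1.38e-13). The dehydration-responsive RD22 (FtPinG0004538200.01) stood at 463 ± 54.5, a metallothionein-like protein (FtPinG0003203100.01) at 184 ± 40.7, PR10a (FtPinG0001096300.01) at 129.96 ± 63.9 and the high-affinity nitrate transporter 2.1-like (FtPinG0002649200.01) at 198 ± 89.4. An endo-1,3;1,4-beta-glucanase (FtPinG0001989200.01) stood at 1149 ± 946, or 611 without the second root library. A proline-rich cell wall gene (BGI_novel_G000479) at 100.1 ± 33.4 was listed at 0 in the others, and the DNA-binding protein AHL23 (FtPinG0008672500.01) stood at 106 ± 53.4. Limma called 3228 genes highest and 1195 lowest in root. All 4 of the lowest with names were photosynthetic: chlorophyll a-b binding proteins 3 (FtPinG0002327100.01, log2 -8.58) and 8 (FtPinG0001195000.01, -8.58), CP29.1 (FtPinG0006533200.01, -8.37) and a ferredoxin-like gene (FtPinG0008116300.01) at 3.24 in root and 5545 ± 326 in leaf.

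Phenylpropanoid entry genes passed higher in root for 7 of 8 members with 0 lower, yet the list test just missed its threshold (mean 2.99, camera adjusted p = 0.0505; adjusted p = 0.774 with an estimated correlation). They included 4-coumarate--CoA ligase (FtPinG0003957300.01) at 474 ± 192 FPKM (log2 3.75), phenylalanine ammonia-lyase (FtPinG0001546000.01) at 377 ± 92.7 (3.33) and cinnamate 4-monooxygenases FtPinG0009242400.01 (5.42) and FtPinG0005329600.01, the latter at 115 ± 84.7 and at 74.3 without the first root library. Of 47 lignin branch genes 26 rose and 9 fell (mean 1.46, adjusted p = 0.823). Caffeic acid 3-O-methyltransferase (FtPinG0009324600.01) reached 966 ± 337, caffeoylshikimate esterase (FtPinG0002821200.01) 242 ± 77.8, a cinnamoyl-CoA reductase 1-like gene (FtPinG0008708600.01) 167 ± 36.9 and cinnamyl alcohol dehydrogenase 1 (FtPinG0006960200.01) 132. Flavonoid core genes gave 1 higher and 2 lower (mean -0.43, median 0.20, adjusted p = 0.344; 1 and 3, -0.89 and -0.37 after median-of-ratios scaling), glycosyltransferases 1 and 1 (0.527), and the anthocyanin branch gene 0 and 0 (0.927; 1 higher at an unadjusted limma p under 0.05; 4.34 FPKM, or 2.80 without root library 3). The anthocyanidin 3-O-glucosyltransferase-like gene (FtPinG0009431800.01) fell by 4.17 log2.

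Water and ion uptake genes passed higher in root for 27 of 60 members and lower for 5 (mean 1.23, camera adjusted p = 0.539), or 21 and 8 with a mean of 0.79 after median-of-ratios scaling. An aquaporin (FtPinG0006228900.01) stood at 810.2 ± 257 FPKM (log2 3.78), PIP2-4-like (FtPinG0009899700.01) at 480.02 ± 58.3 and AQU21 (FtPinG0008427100.01) at 311 ± 114, members of the water channel family, and a sulfate transporter 3.1-like gene (FtPinG0007572400.01) at 228. Aquaporin PIP1-3 (FtPinG0001689700.01) went the other way, at 141 ± 25.2 against 523 to 555 elsewhere, as did sulfate transporters FtPinG0002020200.01 (log2 -2.18) and FtPinG0003394100.01 (-2.90). The other 2 that fell were a phosphate transporter (FtPinG0003424700.01, -1.03), whose call was lost without any 1 of 4 libraries (-0.88 without leaf library 3), and aquaporin NIP7-1 (FtPinG0009643300.01), listed at 10.2 in flower and 0 in the other tissues. Endodermis and peroxidase genes gave 22 higher and 6 lower of 46 (mean 1.46, adjusted p = 0.759), among them peroxidase 21 (FtPinG0006020500.01) at 224 ± 91.9. The Casparian strip integrity factor-like gene (FtPinG0004281700.01), of a peptide family that guides the endodermal barrier, stood at 420.2 ± 158 (log2 6.48). MYB and bHLH regulators gave 41 higher and 7 lower of 93 (adjusted p = 0.189), including MYB59 (FtPinG0008427400.01, log2 4.63), MYB1R1 (FtPinG0004874500.01) at 109.8 ± 16.6 and BHLH021 (FtPinG0007367600.01) at 91.4.

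Photosynthesis was low in root. Of 34 light reaction genes 29 fell and 2 rose (mean -4.99, camera adjusted p = 7.19e-23; adjusted p = 0.106 with an estimated correlation), both rises being root-type ferredoxin--NADP reductases (FtPinG0004266100.01 and FtPinG0008106000.01). Of 11 Calvin cycle genes 7 fell and 2 rose (mean -2.65, adjusted p = 5.85e-05; adjusted p = 0.234 with an estimated correlation). Starch and sucrose genes tested lower, with 10 of 37 down and 6 up (mean -0.35, adjusted p = 0.00719; adjusted p = 0.774 with an estimated correlation), such as beta-amylase 3 (FtPinG0008513000.01), a starch-degrading enzyme, at 1.59 FPKM in root and 70.9 in leaf. Heat shock genes also tested lower, 8 of 38 down and 6 up (mean -0.06, adjusted p = 0.0197; adjusted p = 0.933 with an estimated correlation), such as HSP90-5 (FtPinG0009429700.01) at 13.0, while the late embryogenesis protein At1g64065 (FtPinG0005087400.01) rose to 234.1 ± 36.8. After median-of-ratios scaling both lists had 12 down and 3 up, with means of -0.67 and -0.49. The heat shock call was lost without root library 1 or 3 when the filter was applied again (camera adjusted p = 0.0502 and 0.0580). Ribosomal proteins tested lower relative to all genes, whose median in root was 0.51 (0.07 after median-of-ratios scaling), with 2 of 81 up and 0 down (mean 0.03, median -0.03, adjusted p = 0.0255; adjusted p = 0.954 with an estimated correlation). The risers were L18a-like genes FtPinG0000251100.01, whose call was lost without root library 2 (log2 0.99), and FtPinG0008914400.01. After that scaling 0 were up and 5 down with a mean of -0.52, and the list call was lost without the third leaf library (adjusted p = 0.0537).

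The remaining lists did not pass in root. Cell cycle genes gave 9 higher and 0 lower of 42 (camera adjusted p = 0.120) and housekeeping genes 47 and 4 of 163 (0.0583), or 3 and 1 and 22 and 6 after median-of-ratios scaling. Secondary wall genes gave 10 and 4 of 34 (mean 0.54, test down, 0.713). Floral MADS genes gave 4 and 5 of 13 (mean 0.27, test down, 0.464), and AGL31 (FtPinG0001785400.01), whose Arabidopsis relatives act in flowering time, stood at 27.5 FPKM in root and 4.45 in flower. Pollen genes gave 2 and 3 of 15 (0.169) and other organisms 0 and 1 of 13 (0.303; mean -0.27, median 0.22). After that scaling the secondary wall mean was 0.12 (median -0.07) and the floral MADS mean 0.01. Pollen genes gave 1 and 3, and other organisms 0 and 2 with a mean of -0.70 and a median of -0.20.

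The genes named as highest in stem included several wall enzymes. Xyloglucan endotransglucosylase 23 (FtPinG0009754700.01), which cuts and rejoins wall xyloglucan, stood at 602 ± 528 FPKM in stem (SD, n = 3) and at most 2.00 elsewhere (log2 7.04, SE 0.795, limma adjusted p = 9.89e-06), with 28.1 in the first stem library and a mean of 369 without the third. Xyloglucan endotransglucosylase B (FtPinG0000127800.01) stood at 971.5 ± 220.2, endoglucanases FtPinG0003772700.01 and FtPinG0000392200.01 at 142 ± 58.3 and 339 ± 73.4 and beta-galactosidase 1 (FtPinG0006790900.01) at 60.1 ± 33.0. The nitrate and peptide transporter family protein 1.2 (FtPinG0001054500.01) stood at 287 ± 21.8 (log2 5.21), a BIG GRAIN 1-like gene (FtPinG0008264700.01) at 24.6 ± 1.71 and profilin-2 (FtPinG0005024200.01), an actin-binding protein, at 161 ± 45.5. Limma called 630 genes highest and 209 lowest in stem, against 403 and 41 with a pseudocount of 5, and 736 lowest with a pseudocount of 0.1. The lowest with names were a TCP transcription factor (FtPinG0006025100.01, log2 -3.72), a PR10 gene (FtPinG0007866700.01, -3.95), gibberellin 2-oxidase 1 (FtPinG0000249600.01, -3.88), which inactivates gibberellin, and a peroxisomal 2-hydroxy-acid oxidase (FtPinG0001004400.01, -3.39).

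Secondary wall genes rose in stem, 15 of 34 with 4 lower (mean 0.65, camera adjusted p = 0.0135; adjusted p = 0.774 with an estimated correlation). They included fasciclin-like arabinogalactan proteins 10 (FtPinG0000263500.01) at 433 ± 107 FPKM and 7 (FtPinG0003341800.01) at 395 ± 68.4, and cellulose synthase A1 (FtPinG0009636500.01) at 241 ± 26.1, an enzyme better known from the primary wall. Cellulose synthase A7 (FtPinG0002655200.01), better known from the secondary wall, was among the 4 lower, at 0.307 in stem and 9.22 in root (5.43 without root library 2). The others were cellulose synthase-like G2 genes FtPinG0003001600.01 and FtPinG0004398100.01 and a COBRA-like gene (FtPinG0005926400.01) whose call was lost without leaf library 3 (log2 -0.92). Housekeeping genes tested higher, 21 of 163 with 6 lower (mean 0.19, adjusted p = 0.0197; adjusted p = 0.933 with an estimated correlation), led by tubulins: alpha (FtPinG0005325300.01) at 3625 ± 333, beta-8 (FtPinG0008486000.01) at 1623 ± 292 and beta-2 (FtPinG0000971300.01) at 164 ± 36.2 (log2 4.69). With a minimum of 5 FPKM that list call was lost (adjusted p = 0.0770). Lignin branch genes gave 5 higher and 16 lower of 47 (adjusted p = 0.169). Laccase-17 (FtPinG0008390000.01), which oxidises monolignols, stood at 98.0 ± 61.0 and at 62.8 without the third stem library, and the methyltransferase FtPinG0009324600.01, at 331 ± 224, was at 206 without that library, which ended its call (log2 0.87). The other risers were a cinnamoyl-CoA reductase 1-like gene (FtPinG0005549000.01) at 25.4 and 2 laccases. Laccase-4-like (FtPinG0006531100.01) stood at 25.1, and without the third stem library at 15.5 with its call lost (log2 0.98). Laccase-17-like (FtPinG0003855600.01) stood at 6.74 and at 3.08 without the first stem library.

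Photosynthesis genes also rose in stem against the mean of the other tissues. Of 34 light reaction genes 20 rose and 1, the root-type reductase FtPinG0008106000.01, fell (mean 1.35, camera adjusted p = 7.86e-09; adjusted p = 0.464 with an estimated correlation), and of 11 Calvin cycle genes 6 rose and 0 fell (mean 1.06, adjusted p = 0.0135; adjusted p = 0.742 with an estimated correlation), such as chloroplast fructose-1,6-bisphosphatase (FtPinG0006528900.01) at 46.8 FPKM in stem, and in root listed at 0 in 2 libraries and at 0.21 in the third. Light reaction means were -4.99 in root and 2.71 in leaf, and 22 light reaction genes were lower in stem than in leaf. Calvin cycle means were -2.65 in root and 1.26 in leaf, and 6 of the 11 genes were lower in stem than in leaf and 3 higher. The bisphosphatase stood at 161 to 178 FPKM in the leaf libraries. Endodermis and peroxidase genes fell, 20 of 46 with 5 higher (mean -0.83, adjusted p = 0.00719; adjusted p = 0.7501 with an estimated correlation), such as peroxidase 42 (FtPinG0006206300.01) at 12.9, while peroxidase 47-like (FtPinG0006668900.01) stood at 88.7 (log2 1.73) and expansin-A13 (FtPinG0004492300.01), a wall-loosening protein, at 43.1. The other 3 that rose were ROOT HAIR DEFECTIVE 3 genes FtPinG0002859600.01 and FtPinG0007270800.01, named for a mutant phenotype, and a class III peroxidase (FtPinG0003641700.01).

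Other lists did not pass in stem. Of 15 pollen genes 4 rose and 0 fell (camera adjusted p = 0.0583), among them pollen-specific protein C13 (FtPinG0007151500.01) at 1357 ± 301 FPKM and profilin-3-like (FtPinG0008342700.01) at 506 ± 110.4, so genes of that list were not confined to flower. MYB and bHLH regulators gave 7 higher and 24 lower of 93 (adjusted p = 0.0504), flavonoid core genes 1 and 3 of 8 (0.313), phenylpropanoid entry 0 and 1 of 8 (0.501; FtPinG0005329600.01, lost without stem library 1 or 2, at limma adjusted p = 0.0751 and 0.0527), glycosyltransferases 0 and 1 of 3 (0.778; mean -0.14, median 0.24, test up) and the anthocyanin branch gene 0 and 1 (0.662). Floral MADS genes gave 2 and 5 of 13 (0.303) and cell cycle genes 0 and 4 of 42 (0.377). Of those 4, 3 were inhibitors of cyclin-dependent kinases, which restrain division (FtPinG0004174200.01, and FtPinG0006658900.01 and FtPinG0005561700.01, whose calls were lost without any 1 of 3 and of 6 libraries, at log2 -0.92 and -0.90 without stem library 2). Starch and sucrose genes gave 6 and 3 of 37 (mean 0.22, median -0.03, 0.303), among them a vacuolar invertase (FtPinG0002937900.01) at 281 ± 86.5. Ion uptake genes gave 7 and 13 of 60 (0.999), or 8 and 13 adjusted over the list alone, heat shock genes 1 and 8 of 38 (0.527), ribosomal proteins 1 and 0 of 81 (0.235; L23a-2-like, FtPinG0003831900.01, at 179 ± 11.7) and other organisms 2 and 0 of 13 (mean 0.14, median -0.12, 0.536).

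**Figure D4:**
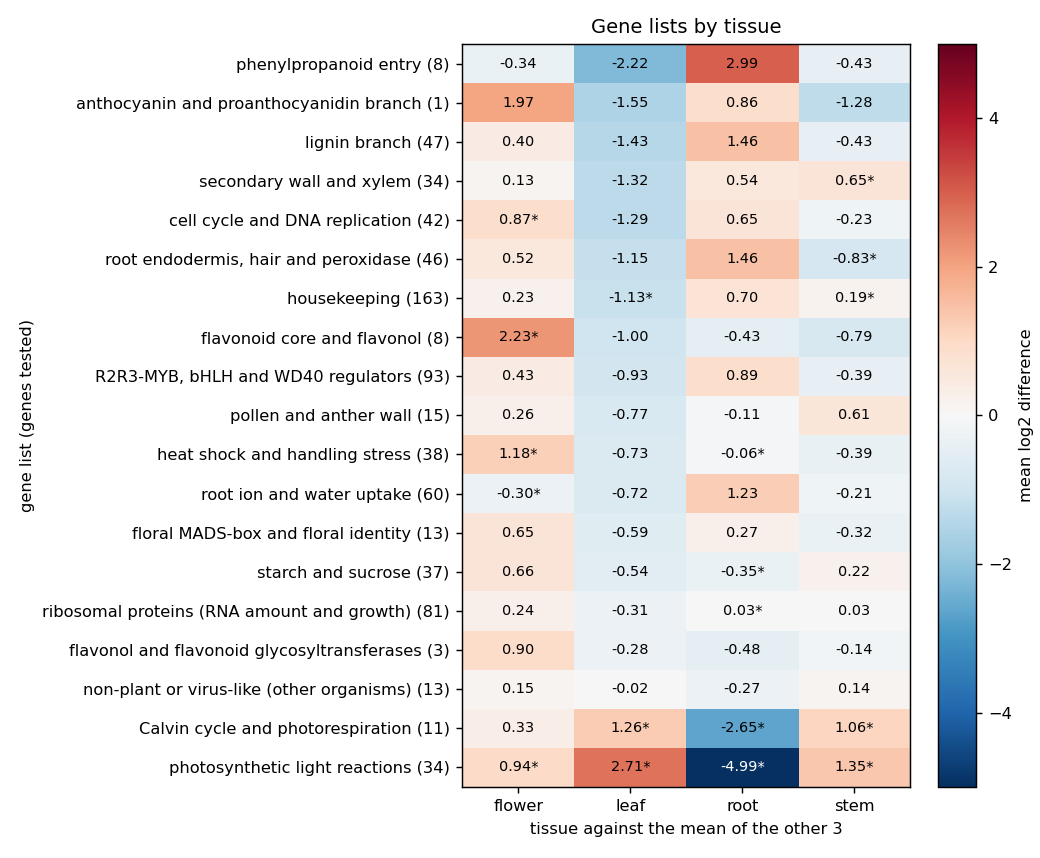
Mean log2 difference of each gene list in each tissue against the mean of the other 3 tissues, with the number of genes tested in parentheses and an asterisk where camera's adjusted p at the preset correlation was under 0.05. Means of light reaction genes were 2.71 in leaf and -4.99 in root, and that of phenylpropanoid entry genes was 2.99 in root.

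Of the 76 list tests 18 passed with camera at the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0740. Of 327 results for named genes, 23 lost their call without 1 library, among them peroxidase 68 (FtPinG0003135700.01) in leaf, with an adjusted p of 0.179 without leaf library 1 and a leaf mean of 57.9 FPKM that was 16.9 without leaf library 3.

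Variant calls asked how far the libraries differed from the reference and from each other. There were 40314 SNP sites, 58.5% of them in 1 library and 4.79% in all 12, and 32052 indel sites, 13.7% of them in all 12. Flower held 12545 ± 1925 SNP sites per library (SD, n = 3), root 10739 ± 354, leaf 8025 ± 574 and stem 7608 ± 574. The exact permutation p was 0.1 (adjusted p = 0.15) for each pair but flower with root and leaf with stem, both at 0.4. Flower and root held 12534 ± 328 and 12530.3 ± 281 indel sites, leaf 9093 ± 222 and stem 9787 ± 367, with an exact permutation p of 0.1 (adjusted p = 0.12) for every pair except flower and root (p = 1). Transitions made up 62.3% to 63.6% of SNPs and insertions 60.8% to 62.3% of indels by tissue. Sites can be called only where reads lie, so counts follow expression as well as sequence, and 35.8% of SNP sites were listed as intergenic.

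Within genes expressed at 5 FPKM or more in all 12 libraries, 5315 SNP sites were listed, and sharing between libraries did not follow tissue alone. The shared fraction was 0.534 between flower libraries 1 and 3 but 0.418 and 0.432 between each of these and library 2. The highest fractions of all pairs lay between tissues, at 0.552 for leaf 1 with stem 1, 0.548 for leaf 2 with stem 3 and 0.544 for flower 2 with root 3. The third leaf library shared 0.375 and 0.352 with the other leaf libraries. Mean sharing was 0.471 within tissues and 0.429 between them.

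**Figure D5:**
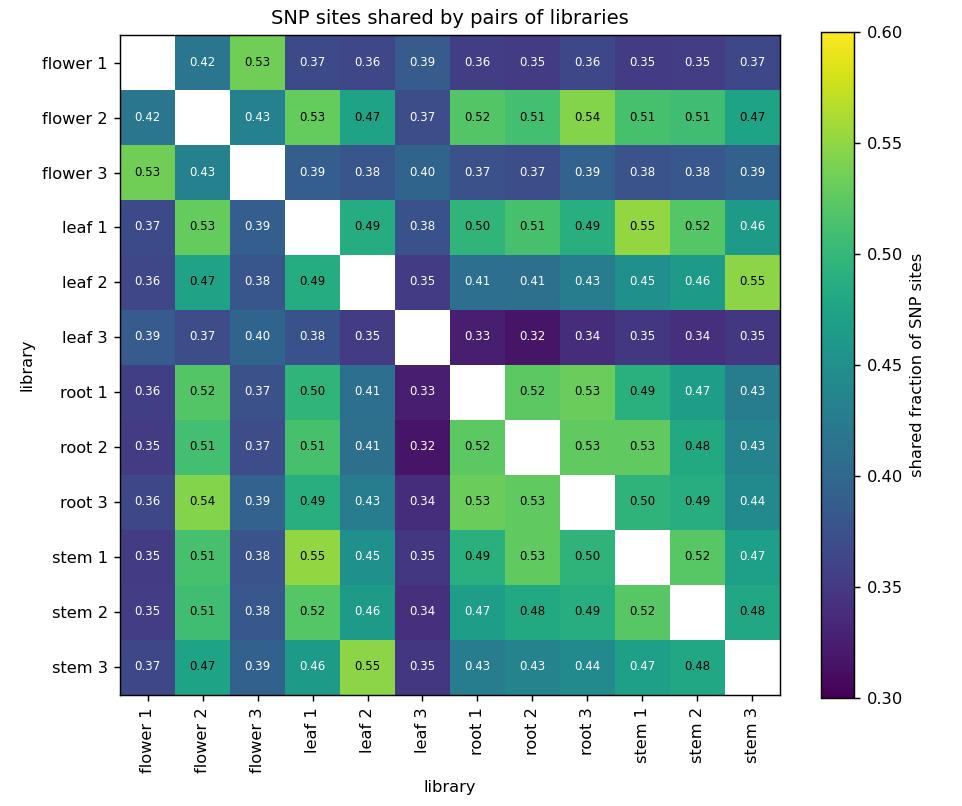
Fraction of SNP sites shared by each pair of libraries, over sites in genes with at least 5 FPKM in all 12 libraries. Flower libraries 1 and 3 shared 0.534 with each other, and the third leaf library shared at most 0.40 with any other.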

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

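Of 977 alternative values of 52 summary results, 879 stayed on their side of the test or within 1.5 times the count, 92 moved and 6 reversed. Differences in genes detected, in the share of the most abundant genes and in SNP and indel sites could only stay or reverse. With 3 libraries against 3 the smallest exact permutation p is 0.1, so none could pass 0.05 under any alternative. They counted as stayed even where their size changed by over 1.5 times, so for them the count does not measure stability. Of 11017 alternative values for named genes, 10717 stayed, 265 lost and 35 gained a call, and 0 reversed. Of 2736 for lists, 2628 stayed, 26 lost and 82 gained a call, and 0 reversed. For lists and named genes, a reversal could be counted only where the main fit made a call. Means of some lists without a call did change sign after scaling, as given above. Chosen only after the result was seen were leave-one-out with the tested genes kept, matching lists at word starts, which kept all 18 list calls, and the restriction to SNP sites in expressed genes. Absolute depth is unknown, so which genes near 0 FPKM are absent could not be decided.

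Reversed differences were all small ones. The share of the 10 most abundant genes in flower minus stem, 1.08 points, was -3.07 for the 100 most abundant genes, and ranged from -1.33 (without flower library 2) to 3.70 without 1 library. The number of genes in flower minus root, 171, was -414 at 5 FPKM, and ranged from 64.3 (without root library 3) to 332 (without flower library 2) without 1 library. Indel sites in flower minus root, 4, ranged from -151 to 186 without 1 library, and were -41.3 without flower library 1 and -132 without flower library 3. Without 1 library 3 other differences moved by over 1.5 times but kept their sign. SNP sites in flower minus root, 1806, ranged from 1164.5 to 2912.5 (without flower libraries 1 and 2), those in leaf minus stem, 417, from 91.8 (without leaf library 3) to 726 (without stem library 3), and the share of the 10 most abundant genes in flower minus root, 5.68 points, from 3.27 to 8.30 (without flower libraries 2 and 3). The cause was not tested.

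Fewer or more genes passed other fold thresholds by construction. With a log2 threshold of 2, genes higher in the first and second tissue numbered 2671 and 392 for flower and leaf, 1815 and 1973 for flower and root, 1339 and 500 for flower and stem, 1399 and 4482 for leaf and root, 548 and 2206 for leaf and stem, and 2215 and 1082 for root and stem. Genes highest and lowest numbered 695 and 15 in flower, 242 and 630 in leaf, 1406 and 598 in root, and 157 and 32 in stem. With no fold threshold, the counts were 14933 and 2214 for flower and leaf, 6317 and 8449 for flower and root, 9413 and 3654 for flower and stem, 3667 and 10680 for leaf and stem, and 11004 and 4240 for root and stem. Highest and lowest were then 3053 and 153 in flower, 1678 and 8754 in leaf, 6667 and 1896 in root, and 1478 and 1092 in stem.

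A pseudocount of 5, which shrinks log2 differences of low genes, gave 3840 genes higher in flower than leaf, 2080 and 2646 for flower and root, 1559 and 1022 for flower and stem, 6302 higher in root than leaf, 1112 and 3461 for leaf and stem, and 2888 and 1494 for root and stem. Highest and lowest were 772 and 26 in flower, 1929 and 723 in root, and 403 and 41 in stem, with 1374 lowest in leaf. The flower call of light reaction genes was lost (adjusted p = 0.103). A pseudocount of 0.1, which widens them, gave 5880 genes higher in flower than stem, 107 lowest in flower, 6044 lowest in leaf and 736 lowest in stem; genes specific by tau were 530 in flower, 14 in leaf, 526 in root and 8 in stem, so that flower no longer had fewer than root. With tau of at least 0.8 they were 109 in leaf and 104 in stem. A minimum of 5 FPKM tests fewer genes and left 2569 higher in flower than stem and 972 highest in flower.

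Scaling changed comparisons with leaf most. Median-of-ratios gave 4183 and 2754 for flower and leaf, 3829 and 5522 for leaf and root, 3638 and 3937 for leaf and stem, and 3940 higher in root than stem, with 123 lowest in flower and 2048 highest and 1279 lowest in leaf. Quantile normalization gave 3243 and 3347, 4095 and 4713, and 3413 and 3516 for the same 3 pairs, 2412 higher in flower than stem, 3402 higher in root than stem, 200 lowest in flower and 2046 highest and 903 lowest in leaf. Of 327 named-gene results 44 lost their call with median-of-ratios and 37 with quantile normalization.

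With the filter applied again without 1 library, genes highest in flower ranged from 733 to 1659 and highest in root from 2136 to 3365 over both kinds of leave-one-out; the low ends come by construction, since genes of 1 tissue then miss the minimum of 3 libraries. With the tested genes kept, 0 of 264 counts moved. The filter applied again without root library 1, 2 or 3 kept 16, 17 and 16 of 18 list calls, those lost being ribosomal proteins (adjusted p = 0.0711, 0.0511 and 0.106) and, without library 1 or 3, heat shock genes (0.0502 and 0.0580) in root. With camera's correlation estimated per list, 0 of 18 list calls held, and 6 of 76 had an unadjusted p under 0.05.

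Using the replicate number as a replicate block changed counts by ratios of 0.997 to 1.06 and ended 0 of 327 named-gene results in limma. Pairing by number was not seen over all pairs, although leaf and stem libraries of number 1 had the highest SNP sharing of all pairs in expressed genes (0.552): SNP sharing between tissues was higher by 0.00128 for libraries of the same number (exact one-sided p = 0.375), and by 0.00430 in expressed genes (p = 0.324, exact). Deviations of expression from the tissue mean differed by -0.00739 (exact p = 0.546), with r over 0.1 in 2 of 18 same-numbered pairs and a range of -0.241 to 0.190. Not run were a stricter depth or quality minimum and heterozygous shares, which the variant tables do not give, and a limit to sites called in all libraries, where counts are equal by construction.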

Other observations

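Gene ontology terms, counted among 3328 tested genes with a term, described further groups among the genes highest in each tissue. In flower, 5 of 11 genes of the response to wounding (hypergeometric adjusted p = 0.00654), 5 of 12 of cell wall modification (0.00955) and 6 of 22 of pectin catabolism (0.0229) were highest. In leaf, 5 of 12 genes of the response to cold and 10 of 50 of cell redox homeostasis were highest (adjusted p = 0.01003 for both). In root, 63 of 242 genes of transcription (9.83e-11), 11 of 24 of hydrogen peroxide catabolism (0.000658) and 13 of 34 of defense (0.000971) were highest. In stem, 6 of 16 genes of the response to auxin (8.29e-05) and 8 of 48 of cell wall organization (0.000554) were highest. Descriptions covered 40.5% to 53.7% of each group of highest or lowest genes, and ontology terms covered fewer. A term was held by 173 of the 1590 genes highest in flower and 181 of 982 in leaf. In root it was 347 of 3228 and in stem 73 of 630. Genes without a term could alter these shares, and the 1590 genes highest in flower were 972 with a minimum of 5 FPKM.

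Tests of the SNP pattern other than coverage, all tests of the leaf pattern, all splits of the libraries and the ontology terms were chosen only after the result was seen.

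SNP sites in well-expressed genes grouped libraries across tissue and number: 224 sites in 149 genes were listed in flower libraries 1 and 3 alone, 176 in these and leaf library 3, 127 in all but leaf library 3, 39 in all but leaf library 2 and stem library 3, and 30 in those 2 with flower libraries 1 and 3. Low coverage of the sites could not be excluded. The genes with sites in flower libraries 1 and 3 alone differed by -0.23 log2 in flower library 2 (quartiles -0.34 and -0.12, median 22.1 FPKM). However, only genes with at least 5 FPKM in all 12 libraries were kept. FPKM of a gene is also not depth at a site, which the variant tables do not give. Among 834 genes with partly shared sites, 16.2% of neighbouring genes had the same set of libraries. The shuffles, 10000 in number, gave a mean of 4.29% and a highest of 6.90% (permutation p = 0.0001, the smallest they can give). That argues against scattered calling errors or editing as the source of all partly shared sites. Most neighbours still differed, and sites in 1 library were left out, so errors at many sites are not excluded. Plants or pools of different genotype behind the libraries of 1 tissue may account for the grouping. The closest pair of libraries by SNP sites was the closest by expression in 4 of 4 tissues (exact p = 0.0123). That test was chosen after a first test, the correlation of the 12 distances within tissues (0.682, exact one-sided p = 0.00694 over 1296 relabellings). Root distances differed little (0.469 against 0.473 and 0.475), both measures come from the same reads, and whether libraries stand for single plants stays open.

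Most genes called in comparisons with leaf were lower in leaf. The mean relative depth of the leaf libraries was 1.01. It was read from FPKM ratios in a bounded window centred on no difference, and was not checked on libraries of known depth. A lower depth of the leaf libraries is therefore not excluded. A few abundant genes taking most of the FPKM could lower the rest, and cannot be told apart from a real difference. Of flower and leaf calls 60.3% were still higher in flower after median-of-ratios scaling, which itself assumes that most genes do not differ. With quantile normalization, which makes the distributions of the libraries equal, that share was 49.2%. After median-of-ratios scaling 17156 ± 106 genes were detected in leaf, 17248 ± 147 in stem, 18926 ± 130 in root and 19466 ± 110 in flower (SD, n = 3). A biological difference between the tissues stays open and was not tested.

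The splits of the 6 libraries of each pair of tissues, 10 in number with the real split included, were too few for a share under 0.05. The real counts were 10029, 8172, 5546, 13717, 8339 and 8350 for flower and leaf, flower and root, flower and stem, leaf and root, leaf and stem, and root and stem, each the only 1 as large, and the highest others were 4, 0, 0, 0, 0 and 49. Of 100 labellings of the 12 libraries, the real labelling included, only the real labelling gave as many genes differing among tissues (21466, highest other 8509). It was also alone for highest in leaf (982, highest other 138) and lowest in leaf (3807 and 27). The same held for highest in root (3228 and 3218), highest in stem (630 and 1) and lowest in stem (209 and 0). The 3218 came from a relabelling that kept the 3 root libraries as root, while another whole tissue under that label gave 693. With the real labelling counted, 2 gave as many genes highest in flower (1590, highest other 3141). For lowest in flower 4 did (57 and 4264) and for lowest in root 2 did (1195 and 3985). Relabellings that mixed tissues under the label gave at most 1 gene for each of these 8 counts. A mixed label puts the tissue differences into the spread within groups, so hardly any gene could pass there. These low counts therefore cannot exclude chance. Higher counts came only where a label held the 3 libraries of 1 tissue, in 4 of 99 relabellings for flower, 2 for root, 1 for leaf and 0 for stem. Since the low counts under mixed labels follow from that spread, the contrast is no separate support for tissue differences. How the real counts rank against relabellings that hold a whole tissue depends on the draw, and the shares are not adjusted for their number.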
